A study of Homo sapiens with 3 samples.

How the data were processed

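Gene expression was measured on 3 single-colour Affymetrix Human Genome U133 Plus 2.0 arrays, hybridised with biotin-labelled total RNA from SK-Mel-28, an established human melanoma cell line. Per the labels, 1 array held RNA from cells stably transfected with a scrambled hairpin vector, and 2 arrays held RNA from cells transfected with a hairpin against melanotransferrin (MTf, gene symbol MELTF). The labels name the siRNA arrays B1 and B2 without saying what the letters stand for, and they are called siRNA array 1 and siRNA array 2 here. Nothing in the labels says whether they came from separate clones or cultures, so p-values measure only the spread between these arrays, which may be technical. The sample labels place the siRNA target at nucleotides 2048 to 2066 of the MELTF transcript, whereas the series' design text gives 2031 to 2049. Which of these is right was not settled here.

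The deposited values are probe set intensities on a linear scale, 1 value per probe set and array. Per the submitters' processing notes they came from GCOS 1.3. On each array the mean signal after trimming 2% of the values at each end was close to 1000 (1000.14, 1000.12 and 1000.13), so that the arrays had been scaled to a common mean before deposit. Other settings of that software are not given in the sources used here, and no detection calls were used. The number of arrays, 1 against 2, limits the precision of every comparison, since the scrambled array has no replicate.

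The table held 54675 probe sets, of which 62 control probe sets were left out. Of the other 54613, the platform annotation given for this work named 1 gene for 41091, several for 1801 and none for 11721. Probe sets with several genes or none were tested but not named. No symbol changed when Entrez identifiers were matched to the current gene table (assembly GRCh38.p14), and 54 identifiers had no match there. That table served only for symbols and for the order of genes along chromosomes. The genome build behind the deposited values is not given in the sources used here, and no coordinates are printed. There were 0 value columns of other samples.

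Signals were analysed as log2(signal + pseudocount), with a pseudocount of 47.4, the 25th percentile of all signals. Log2 differences and folds are on this log2(signal + pseudocount) scale, which understates changes of dim probe sets. Control probe sets for a bacterial gene (trp) read 7.0 to 97.2. For named genes with signals below 97.2 on the dimmer side, the log2 difference depends on the pseudocount and is not printed. Their change is given as a lower bound on the mean change over the 2 siRNA arrays, at least N-fold, so that a single array can show less. It was taken from the geometric mean of the signals with each raised to at least 97.2, a level chosen after the data were seen. Probe sets with a mean log2 value above the median (7.74) were kept, which left 27306 probe sets and 12386 genes. A gene was represented by its probe set with the highest mean, and disagreement among its probe sets is given where it was found for a gene described at length. The siRNA arrays were compared with the scrambled array by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean signal) and Benjamini-Hochberg adjustment at 0.05. All adjusted p-values for genes and probe sets are two-sided values from this limma test. It has 1 residual degree of freedom per probe set, from the 2 siRNA arrays, to which the moderation added 6.36, and the lone scrambled array was assumed to vary like them. Errors given as SE come from this model.

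Probe sets that differed at least 2-fold from the scrambled array on both siRNA arrays were counted without a test. Because both differences use the same scrambled array, 100 sets of unchanged arrays sharing 1 control were simulated with the fitted spread. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists with at least 5 measured genes. With an estimated correlation camera has only the 1 residual degree of freedom, so it could hardly pass any list and decides little about correlation. Each list's median was also placed among 10000 random lists of the same size matched on mean signal. The 22 lists covered iron metabolism, melanocyte differentiation and pigmentation, dedifferentiated or invasive melanoma, cell cycle (G2/M and mitosis), DNA replication, interferon response, MHC antigen presentation, hypoxia, endoplasmic reticulum stress, cholesterol synthesis, p53 targets, the plasminogen system, extracellular matrix and adhesion, WNT and TCF signalling, MEF2 factors, glutamine metabolism, apolipoproteins and lipid transport, small RNA machinery, and markers of epithelial, fibroblast, leukocyte and endothelial cells.

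The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took MELTF in all its probe sets, then the 15 genes higher and the 15 lower with the largest value of the smaller of their 2 log2 differences from the scrambled array. It added up to 4 genes per list by the same measure, and MEF2A, TCF4, APOD, TFRC, MITF, TYR and MLANA whatever their values. A further 2 genes fixed by name are not analysed here. Genes named outside this rule are said to be so. The alternatives were quantile normalization, centring arrays on their medians, no pseudocount or a larger one, no filter or a stricter one, limma without the trend or with robust moderation, the mean of a gene's probe sets, and leaving out each siRNA array. The gene list tests without the trend were added after the data were seen.

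The limma step was tested on simulated data made from these arrays' means and fitted spread, with 27306 probe sets and 20 repeats. With 200 changed probe sets it recovered 0.2% of 2-fold, 54.8% of 4-fold and 78.4% of 8-fold changes. The false share of calls was 70.4%, 11.5% and 9.99% in these 3 cases, above the nominal 5%. With 2000 changed probe sets it recovered 5.83%, 87.5% and 98.8%, and 12.0%, 6.96% and 5.99% of the calls were false. Small changes were therefore mostly not detectable with 3 arrays, and the false share of calls can exceed its nominal level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.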

Results

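Expression profiles of SK-Mel-28 melanoma cells carrying a hairpin against melanotransferrin (MELTF, an iron-binding transferrin homologue anchored to the cell surface) were compared with that of cells carrying a scrambled hairpin. The comparison asked which transcripts differ when MELTF is targeted by stably expressed siRNA. There was 1 scrambled array and 2 siRNA arrays, each with signals for 54613 non-control probe sets. The median signal was 160.6 on the scrambled array and 174.3 and 199.5 on siRNA arrays 1 and 2. The siRNA arrays were closer to each other (Pearson r = 0.969 across probe sets past the filter, which are not independent replicates) than to the scrambled array (r = 0.948 and 0.936). The ratio of the 3' to the 5' GAPDH control probe set was 1.03, 1.01 and 1.01. Ribosomal RNA control probe sets were brighter on siRNA array 1 than on the scrambled array, with a median ratio of 4.01.

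MELTF itself was measured by 4 probe sets, which did not move together. The brightest had a signal of 32608 on the scrambled array against 18968 and 18974 on the siRNA arrays, or 58.2% of the scrambled signal (log2 difference -0.78 ± 0.17, SE; adjusted p = 0.0699). The second brightest was higher on both siRNA arrays, at 10567 and 11199 against 8284 (log2 difference 0.39 ± 0.20, SE; adjusted p = 0.318). A dimmer probe set read 915.2 on the scrambled array and 699.7 and 283.6 on the siRNA arrays (adjusted p = 0.326). The dimmest read 546.4 against 693.7 and 665.7 (adjusted p = 0.640). No MELTF probe set passed the threshold as deposited. Among the alternatives run for MELTF, which left out robust moderation, the brightest passed it only with arrays centred on their medians (log2 difference -0.94, adjusted p = 0.0397). The mean of the 4 probe sets differed by -0.26 (adjusted p = 0.573).

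**Figure D1:**
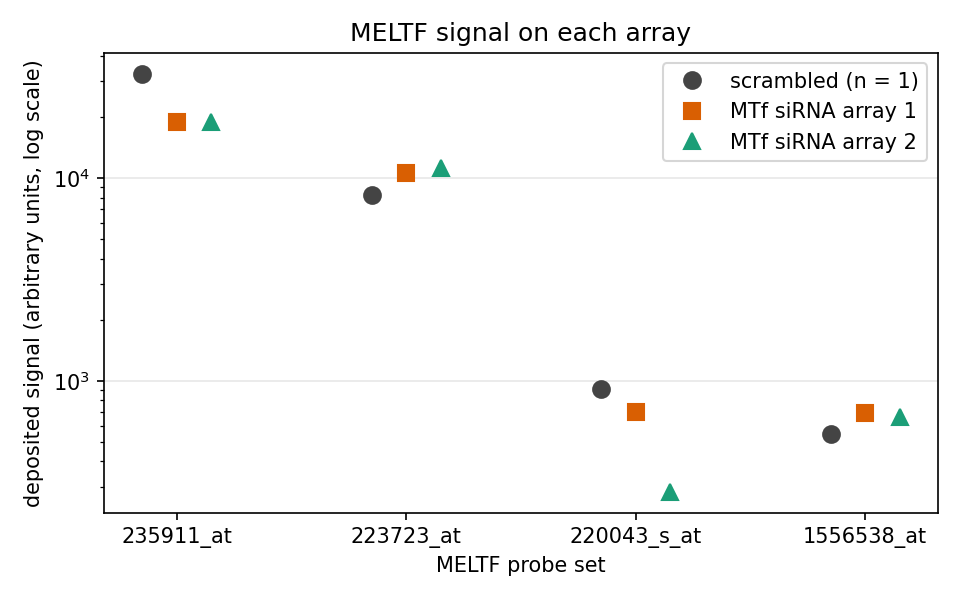
Deposited signal (arbitrary units, log scale) of the 4 MELTF probe sets on the scrambled array and on each siRNA array, 1 point per array. Probe sets are ordered by their scrambled signal: the brightest lies lower on both siRNA arrays (18968 and 18974 against 32608), and the second brightest lies higher (10567 and 11199 against 8284).

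The 29 measured genes nearest to MELTF on its chromosome, from ACAP2 to LMLN, had a median log2 difference of -0.52 on the siRNA arrays, a comparison chosen after the values of MELTF were seen. Of these, 23 were below 0 and 6 above, 2 passed the threshold (NCBP2 and LMLN, both lower) and 15 had an unadjusted p under 0.05. MELTF lay 0.26 below that median (difference -0.26), 8 of the 29 were at least as low as MELTF, and 1, PIGZ, was higher by as much. With quantile normalization the neighbours' median was -0.49 and with arrays centred it was -0.69. TFRC, the transferrin receptor, is among these neighbours and differed by -0.47 ± 0.20 (SE; adjusted p = 0.239). The lipocalin gene APOD is another, at 0.073 ± 0.24 (SE; adjusted p = 0.902), or -0.090 with arrays centred.

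**Figure D2:**
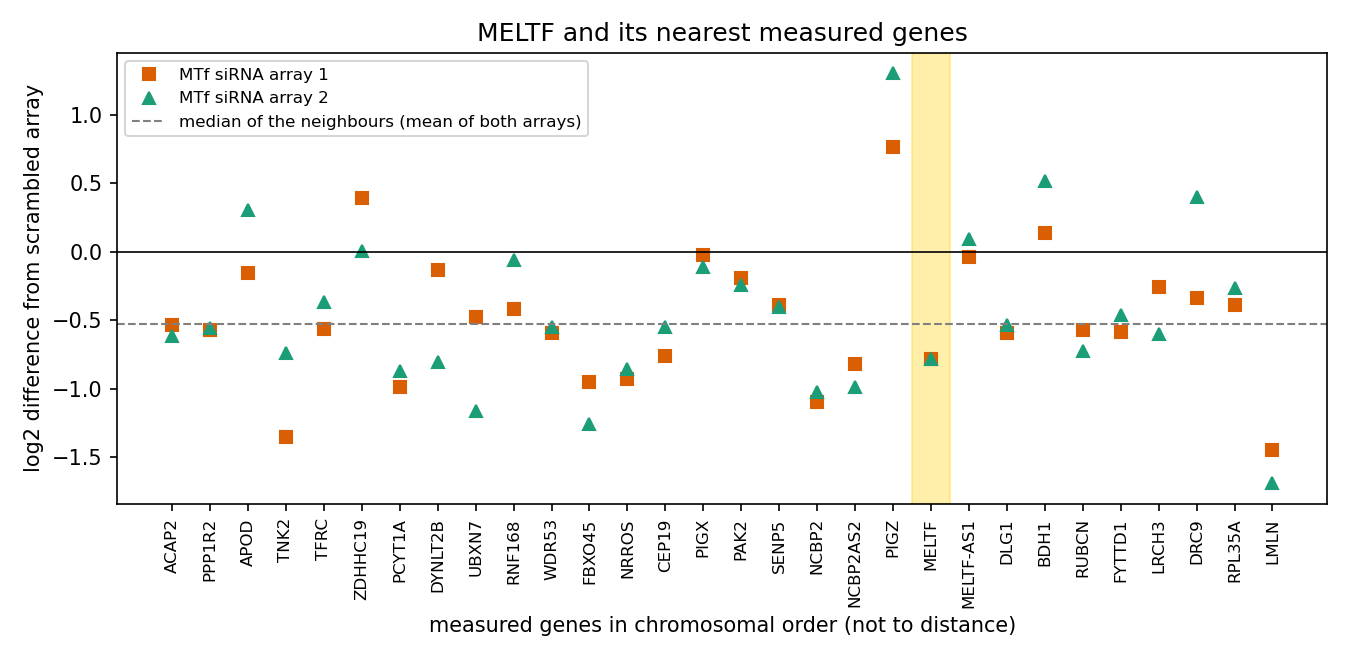
Log2 difference of each siRNA array from the scrambled array for MELTF (shaded) and its 29 nearest measured genes in chromosomal order, not drawn to distance; squares and triangles are the 2 siRNA arrays and the dashed line is the neighbours' median of -0.52. Of the 29 neighbours, 23 have a mean difference below 0.

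Across the genome, 571 of 27306 probe sets (2.09%) passed the threshold, 324 higher and 247 lower in the siRNA cells, and 5511 had an unadjusted p under 0.05. Counted by gene, 327 of 12386 passed, 186 higher and 141 lower. A difference of at least 2-fold on both siRNA arrays was seen for 1573 probe sets, 1073 higher and 500 lower. Unchanged arrays sharing 1 control gave 296 in simulation (range 255 to 332), and independent lists of the sizes found on each array would overlap by 136 higher and 38.4 lower. The differences of the 2 siRNA arrays correlated at r = 0.760 across probe sets, against 0.50 in the simulation, with a covariance of 0.322 against 0.104. Part of any excess may come from the shared scrambled array, which could not be split.

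The number of calls rested on the filter and on the model of the spread: limma called 1 probe set without a filter, 9 with a filter at the 75th percentile, and 1 without the trend. The median probe set was 0.11 higher on the siRNA arrays on the log2 scale, and centring the arrays turned the balance of calls from 324 higher and 247 lower to 254 higher and 468 lower. The 2-fold counts turned as well, from 1073 higher and 500 lower to 703 and 817 with arrays centred, and were 775 and 622 with quantile normalization.

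The highest-ranked increase was in PRDX2, a peroxiredoxin that reduces hydrogen peroxide. Its brightest probe set read 7.0 on the scrambled array and 6579 and 5930 on the siRNA arrays, at least 64.3-fold higher (adjusted p = 0.000466), and it was the 1 probe set still called without the filter or without the trend. A dimmer PRDX2 probe set rose as well (23.3 against 1171 and 1371, at least 13.0-fold), whereas a further one read 508.9 against 486.2 and 500.3. TRPV4, a calcium-permeable cation channel, rose from 15.8 to 1717 and 1875, at least 18.5-fold (adjusted p = 0.00490). The zinc finger gene ZNF468 rose at least 21.3-fold and NSG1, a neuronal endosomal protein gene, at least 16.5-fold. COL9A3, which encodes a chain of type IX collagen, rose at least 12.8-fold. Among genes already bright on the scrambled array, the protease inhibitor genes SERPINA3 (462.2 against 4403 and 10359) and CST1 (592.8 against 5393 and 8542) rose, as did the carboxypeptidase gene CPVL (653.6 against 5876 and 6655). TRIM47, MAGEL2, STK32B, the Ras-related GTPase gene RRAS, the organic anion transporter gene SLCO4A1, CPNE2 and LINC03002 completed the 15 highest-ranked. All 15 passed the threshold (largest adjusted p = 0.0329), and 11 of them had a scrambled signal below the highest bacterial control signal, 97.2, so that their order rests on the pseudocount.

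The largest decreases were in genes bright on the scrambled array. UCHL1, a ubiquitin hydrolase abundant in neurons, fell from 4222 to 34.4 and 143.5, at least 35.7-fold lower in the geometric mean of both arrays (adjusted p = 0.0169). GDF15, a stress-induced cytokine of the TGF-beta superfamily, fell from 26790 to 1888 and 802.3 (log2 difference -4.39 ± 0.44, SE; adjusted p = 0.0169). IL24, a cytokine of the interleukin-10 family, fell from 9250 to 672.5 and 710.0 (log2 difference -3.65 ± 0.25, SE; adjusted p = 0.00584). The neurotrophin gene BDNF fell by 3.44 on the log2 scale in its brightest probe set and fell by 3.78 in another. TFPI2, a Kunitz-type protease inhibitor, fell from 28362.5 to 3356 and 1446. RGS2, a regulator of G protein signalling, fell from 34189 to 5322 and 2566. BEX1, DGKI, ZNF804A, ALDH1L2, NAP1L2, the kinase gene DYRK3, BAAT, PWWP3B and HECW2 made up the rest of the 15, all past the threshold with a largest adjusted p of 0.0493. On at least 1 siRNA array 5 of the 15 had a signal below 97.2.

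**Figure D3:**
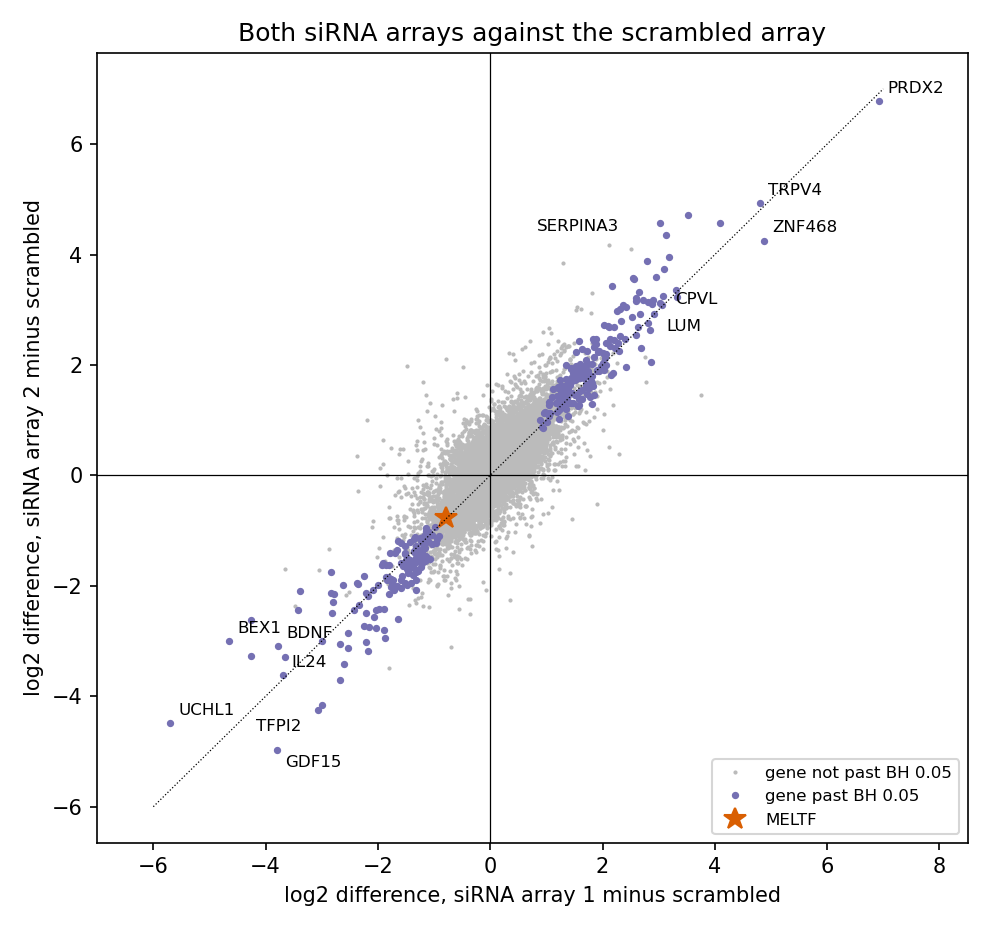
Log2 difference from the scrambled array on siRNA array 1 (horizontal) and siRNA array 2 (vertical), 1 point per gene; larger purple points are the 327 genes past the limma threshold, the star is MELTF and the dotted line marks equal differences. Both axes share the scrambled array, so some correlation arises without any effect. PRDX2 lies at the top right and UCHL1 and GDF15 at the bottom left, where the distances of genes dim on either side depend on the pseudocount.

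Interferon response genes lay higher in the siRNA cells. The 26 measured genes had a median log2 difference of 0.65 (0.45 on siRNA array 1 and 0.84 on siRNA array 2, against 0.097 over all genes; camera adjusted p = 0.00109, and adjusted p = 0.946 with an estimated correlation). Over all genes tested, 0 of the 26 passed limma's threshold and 12 had an unadjusted p under 0.05. Adjusted over the list alone, 9 rose and 1 fell. The antiviral genes IFIT1 (14.2 against 304.1 and 1014) and MX1 (67.1 against 348.9 and 397.3), and the ubiquitin-like pathway genes USP18 (337.3 against 1042 and 890.6) and ISG15 (1012 against 2444 and 2530), had the largest values of the smaller of their 2 differences. IFIT1 and MX1 lay below the highest bacterial control signal, 97.2, on the scrambled array. With the 75th percentile filter, which left 13 genes, the list's call was lost (adjusted p = 0.0634).

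MHC antigen presentation genes (20 measured) had a median log2 difference of 0.39, short of the threshold (camera adjusted p = 0.0749). Over all genes tested 0 passed limma's threshold (5 at an unadjusted p under 0.05), and adjusted over the list alone 2 rose. B2M, the light chain of MHC class I, read 26604 against 42059.5 and 46806 (adjusted p = 0.0738). HLA-DPA1 read 4601 against 7768.5 and 9183 (adjusted p = 0.0880). Iron metabolism genes (20 measured) had a median of 0.44 (camera adjusted p = 0.0887), with 0 past limma's threshold over all genes (7 at an unadjusted p under 0.05) and 4 higher adjusted over the list alone. These were CYBRD1, a duodenal ferric reductase (log2 difference 1.28 ± 0.25, SE; adjusted p = 0.0526), the ferrireductase STEAP3 (1.12 ± 0.29), the last enzyme of haem synthesis FECH (0.99 ± 0.28) and the iron chaperone PCBP2 (0.67 ± 0.18). With quantile normalization both lists passed, at camera adjusted p = 0.0224 for MHC genes and 0.0234 for iron genes. With an estimated correlation, which leaves 1 residual degree of freedom, camera adjusted p was 0.953 for both.

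Pigmentation genes went both ways. Of 23 measured, 3 rose and 1 fell over all genes tested, and 6 rose and 3 fell adjusted over the list alone. TYRP1, a melanosomal enzyme, fell from 53204 to 5022 and 12370 (log2 difference -2.75 ± 0.45, SE; adjusted p = 0.0374). The cation channel gene TRPM1 (2.02 ± 0.26), the endothelin receptor gene EDNRB (1.49 ± 0.25) and the receptor gene ERBB3 (1.40 ± 0.25) rose. Tyrosinase, TYR, differed by 0.86 ± 0.17 in its brightest probe set (adjusted p = 0.0529), rose by 1.11 in a second (adjusted p = 0.0383) and differed by -0.11 in another. The melanocyte transcription factor gene MITF differed by -0.46 ± 0.19 (adjusted p = 0.236) and MLANA by 0.099 ± 0.16 (adjusted p = 0.780), or -0.065 with arrays centred. The list's median was 0.099 (camera adjusted p = 0.605).

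The G2/M and mitosis list had a lower median in the siRNA cells, at -0.46 over 25 genes (camera adjusted p = 0.00109, and adjusted p = 0.946 with an estimated correlation). That median was -0.71 on siRNA array 1, the array with brighter ribosomal control probe sets, and -0.067 on siRNA array 2. None of its genes passed limma's test (0 of 25, and 0 adjusted over the list alone), and 4 had an unadjusted p under 0.05. CDK1, the mitotic kinase, read 9164 against 3139 and 5520 in its brightest probe set (adjusted p = 0.122). Other CDK1 probe sets differed less, by -0.46 (adjusted p = 0.482) and -0.41 (adjusted p = 0.536). DNA replication genes had a higher median, 0.48 over 24 genes (camera adjusted p = 0.0246, and adjusted p = 0.946 with an estimated correlation), at 0.18 on siRNA array 1 and 0.79 on siRNA array 2. The helicase subunit gene MCM6 rose (log2 difference 1.35 ± 0.25, SE; adjusted p = 0.0459), the only 1 of the 24 to pass, over all genes and over the list alone. This list's call was lost with the 75th percentile filter (adjusted p = 0.0823) and without the trend (adjusted p = 0.0685).

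**Figure D4:**
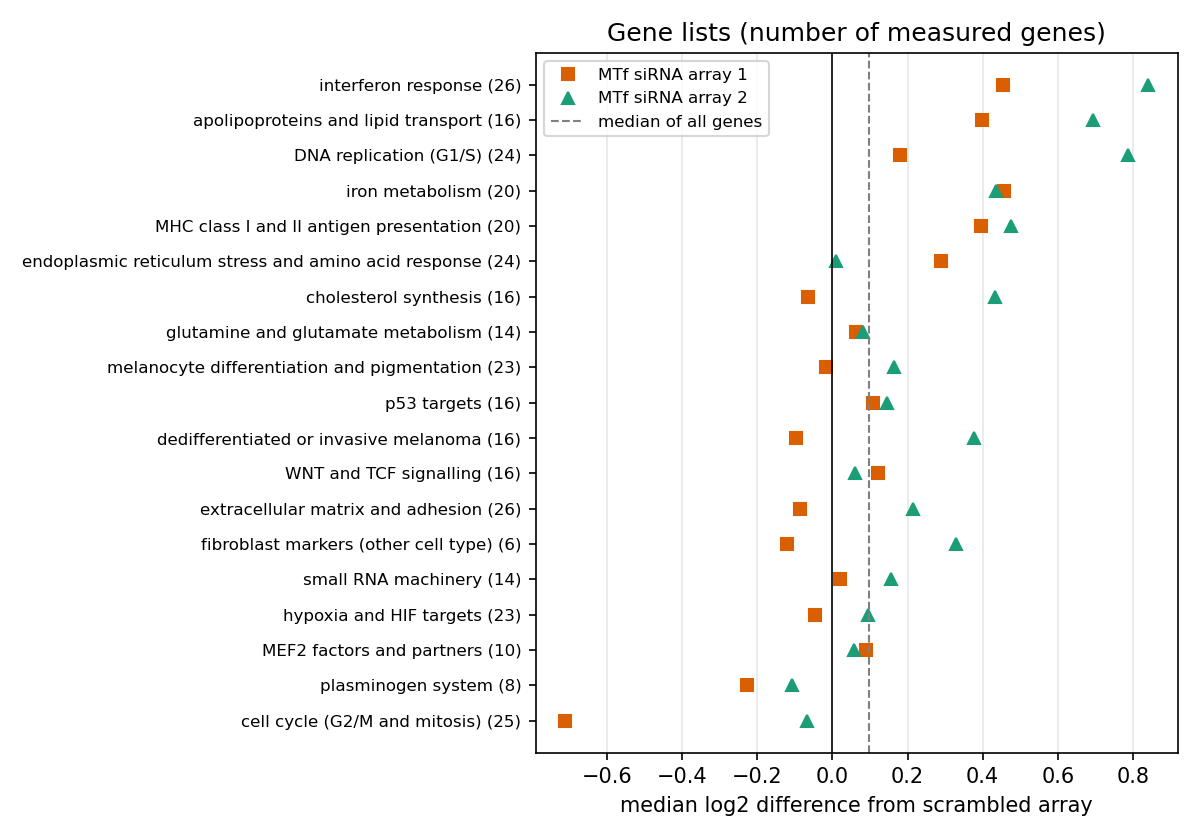
Median log2 difference from the scrambled array of each tested gene list (number of measured genes in parentheses) on siRNA array 1 (squares) and siRNA array 2 (triangles); the dashed line is the median of all genes, 0.097. Interferon response genes lie highest on siRNA array 2 (0.84), iron metabolism and interferon response genes lie highest and close together on siRNA array 1 (0.46 and 0.45), and the G2/M and mitosis list is the lowest on siRNA array 1.

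Several genes of signalling and stress lists fell. In the WNT and TCF list (16 measured), the WNT antagonist gene DKK1 fell from 35851 to 8523 and 6021 (log2 difference -2.32 ± 0.25, SE), and MYC fell by 1.24. TCF4, a gene distinct from TCF7L2 of the same list, rose at least 4.56-fold (adjusted p = 0.0284), from a scrambled signal of 15 to 392.3 and 499.8. These were the 3 that passed, over all genes and over the list alone. Among 10 MEF2 factors and partners, MEF2C fell (-1.52 ± 0.20, adjusted p = 0.0245) and MEF2A differed by -0.083 ± 0.22 (adjusted p = 0.879; 0.33 as the mean of its probe sets); over the list alone 2 rose and 2 fell. Of 16 p53 targets, GDF15, AEN (-1.48) and the growth arrest gene GADD45A (-1.41) fell, and over the list alone 1 rose and 3 fell. The 16 measured genes of dedifferentiated or invasive melanoma included 2 that fell on either adjustment, the AP-1 gene FOSL1 (-2.24 ± 0.25) and CCN1 (-1.40 ± 0.24). No difference from other genes as a set was detected for any of these lists. Their medians were 0.066 (WNT and TCF), 0.0061 (MEF2), 0.099 (p53) and 0.074 (dedifferentiated or invasive), with camera adjusted p of 0.905, 0.605, 0.605 and 0.605.

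In the other lists few genes passed, and medians near 0 there and in the preceding lists changed sign with the scaling or with an array left out. In the adhesion and matrix list (26 measured, median 0.063), the neural adhesion gene L1CAM rose (2.18 ± 0.29) and ALCAM fell (-1.82 ± 0.22), and over the list alone 1 rose and 3 fell. A dimmer L1CAM probe set differed by only 0.26 (adjusted p = 0.770). Hypoxia genes (23, median 0.018) included ERO1A, which rose by 1.16 in its brightest probe set, and 3 higher over the list alone. Other ERO1A probe sets differed by 0.31 (adjusted p = 0.539) and 0.92 (adjusted p = 0.124). In the endoplasmic reticulum stress list (24, median 0.25) XBP1, a transcription factor of the unfolded protein response, rose by 1.51, the 1 gene to pass on either adjustment. The amino acid transporter gene SLC38A1 fell by 1.99 on the log2 scale in the glutamine list (14, median 0.15), also the 1 gene on either adjustment. The lysosomal cholesterol transport gene NPC1 fell by 1.29 among apolipoproteins and lipid transport genes (16, median 0.58, camera adjusted p = 0.368), where 3 rose and 2 fell over the list alone. Cholesterol synthesis (16, median 0.17) and small RNA machinery (14, median 0.041) had 0 genes past limma's threshold on either adjustment, with 2 in each list at an unadjusted p under 0.05. The plasminogen system (8, median -0.17, or -0.23 on siRNA array 1 and -0.11 on siRNA array 2) had 0 over all genes by limma, 2 at an unadjusted p under 0.05, and 2 lower over the list alone. Apart from the 3 lists named as past the camera threshold, none of the 19 tested was called, and in 8 lists the median and the test against other genes differed in sign. In 4 lists the median and the mean differed in sign. Among random lists matched on mean signal, which make no allowance for correlation, the called lists lay at percentiles 100 (interferon), 0 (G2/M) and 99.79 (DNA replication). Of lists not called, the highest were 99.98 (apolipoproteins and lipid transport), 99.87 (iron), 99.68 (endoplasmic reticulum stress) and 99.18 (MHC). The others lay between 18.97 (plasminogen) and 91.17 (pigmentation).

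Markers of other cell types were few past the filter. Among 6 fibroblast markers (median 0.046, camera adjusted p = 0.503) the proteoglycan gene LUM rose from 598.6 to 4850 and 4841 (log2 difference 2.92 ± 0.24, SE; adjusted p = 0.00719). Over the list alone 2 rose, LUM and the transcription factor gene TWIST1 (958 against 1832 and 2022), while COL1A1 read 671.9 against 487.9 and 565.1. The list's mean was 0.57. Among 4 epithelial markers ESRP1, a splicing factor, fell from 14486 to 5567 and 4656, and over the list alone 1 rose and 1 fell. Of 4 leukocyte markers 0 passed limma's threshold over all genes (1 at an unadjusted p under 0.05), and LCP1 fell over the list alone (1130 against 477.8 and 384.7). The 1 endothelial marker measured, PECAM1, differed by 0.57 (adjusted p = 0.487). The epithelial, leukocyte and endothelial lists were too small for the set test.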

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

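The tests of other splits of the arrays and of the share of siRNA array 1 differences seen on siRNA array 2 were chosen after their results, or values close to them, had been seen. The ribosomal RNA control probe sets, which no comparison uses, had a median signal 4.01 times that of the scrambled array on siRNA array 1. The separate ratios ran from 2.09 to 4.91 there and from 0.84 to 1.24 on siRNA array 2.

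One pattern to weigh is that many probe sets differ from the scrambled array on both siRNA arrays. Carry-over of ribosomal RNA or another flaw of siRNA array 1 could produce differences on that array, but probe sets at least 2-fold different there moved on siRNA array 2 by a median of 0.908 of the same difference, against at most 0.549 in simulations of unchanged arrays sharing the control, which argues against it as the main cause. A copy number difference changes neighbouring genes together. Of the genes at least 2-fold different on both arrays, 38.1% lay within 5 measured genes of another changed the same way. That was under the 50% set for this cause, though above the 35.9% highest of 1000 shuffles, so that a part may follow chromosomal blocks. Smaller shifts of a region escape this test, so it cannot say how much copy number contributes. Of the 3 splits of the arrays into 1 and 2, only 1, the real one, gave as many calls (571), and limma called 0 in each of the others (346 and 828 at an unadjusted p under 0.05), but 3 splits are too few for a share under 0.05. The hairpin against MELTF stays open as an explanation, untested, because a departure of the single scrambled line or array from the parental cells would give the same pattern.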

How the results depend on the processing

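The alternatives here were planned, except the gene list tests without the trend, which were chosen after seeing the data. Of 215 values of the main results under alternatives, 175 were classed as unchanged. They kept their direction and side of the threshold or, for counts, stayed within a fixed fold. With an array left out, differences had to stay within the spread of the siRNA arrays, which MELTF, a mean over both, did by construction. List medians mostly lay near the middle of the 2 arrays and so met this rule almost by construction, which says little about stability. The called lists were classed as unchanged although they ranged from -0.71 to -0.067 (G2/M), 0.18 to 0.79 (DNA replication) and 0.45 to 0.84 (interferon). Sign changes of list medians with an array left out were not counted as such and are given below. Another 15, all medians of lists not past the threshold, changed sign with both siRNA arrays in use. With arrays centred these were -0.065 (pigmentation), -0.090 (dedifferentiated), -0.15 (hypoxia), -0.065 (p53), -0.10 (adhesion and matrix), -0.098 (WNT), -0.16 (MEF2), -0.015 (glutamine), -0.12 (small RNA) and -0.12 (fibroblast). With quantile normalization they were -0.0069 (dedifferentiated) and -0.14 (fibroblast), without a filter -0.12 (fibroblast), with the 75th percentile filter -0.054 (WNT) and with the mean of a gene's probe sets -0.015 (hypoxia). APOD (-0.090) and MLANA (-0.065) with arrays centred and MEF2A (0.33) with the mean of its probe sets also changed sign. The calls were most fragile: limma called 571 probe sets as reported, 357 with quantile normalization, 1 without a filter, 9 with the 75th percentile filter and 1 without the trend. In these last 3 settings the moderation added fewer degrees of freedom (4.79, 4.65 and 4.02 against 6.36). Probe sets at least 2-fold different on both arrays numbered 1573 as reported, 957 with the pseudocount at the median, 3210 without a filter, 659 with the 75th percentile filter and 2578 to 3379 with either siRNA array left out, where a single array had to pass. MELTF reached -0.94 (past the threshold) with arrays centred, and its adjusted p ranged from 0.0397 to 0.573. List medians newly past the threshold were 0.44 (iron) and 0.38 (MHC) with quantile normalization and 0.40 (MHC) without a filter, none of them past it with an estimated correlation and its 1 residual degree of freedom. Those no longer past it, with the 75th percentile filter and fewer genes, were 0.39 (DNA replication) and 0.68 (interferon). Without the trend DNA replication, at 0.48 with the same genes, was not past it either (adjusted p = 0.0685). With either siRNA array left out, medians ranged from 0.40 to 0.47 (MHC), 0.0087 to 0.29 (endoplasmic reticulum stress), 0.11 to 0.15 (p53), 0.057 to 0.088 (MEF2), 0.064 to 0.082 (glutamine), 0.019 to 0.16 (small RNA), 0.059 to 0.12 (WNT) and -0.23 to -0.11 (plasminogen). Medians that changed sign between the arrays ranged from -0.098 to 0.38 (dedifferentiated), -0.066 to 0.43 (cholesterol), -0.085 to 0.22 (adhesion and matrix), -0.018 to 0.16 (pigmentation), -0.046 to 0.094 (hypoxia) and -0.12 to 0.33 (fibroblast). Other causes were not tested. Of 119 named genes besides MELTF, 51 passed as reported, and 50 of these did not pass without a filter or without the trend. No paired analysis was possible because no label pairs the siRNA arrays with the scrambled array. Control probe sets for a bacterial gene read 7.0 to 97.2, so signals below about that level carry little information.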

Other observations

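In this part the test of the genes beside MELTF was chosen after its values were seen. The immediate-early and ERK output lists were chosen after the largest decreases were seen. Genes already looked at by name were left out, but ATF3, also in the planned endoplasmic reticulum stress list, was kept. Immediate-early genes are transcribed within minutes of growth factor or stress signals. Of 17 measured, 2 passed the threshold, both lower, and 16 had a log2 difference below 0, with a median of -0.998 (-0.87 with quantile normalization and -1.16 with arrays centred). NR4A3 fell from 35171 to 9559 and 4516 (adjusted p = 0.0367) and FOS from 7493 to 3455 and 3250 (adjusted p = 0.0493). EGR1 read 24800 against 14020 and 7001 (adjusted p = 0.110), and KLF4 was the exception, at 0.66 (adjusted p = 0.219). Genes of ERK pathway output (15 measured, 0 past limma's threshold and 5 at an unadjusted p under 0.05) had a median of -0.33, with 10 below 0. DUSP6 was at -0.72 (adjusted p = 0.0943) and SPRY2 at -0.83 (adjusted p = 0.0774), whereas ETV1 (0.24) and ETV5 (0.14) were among those that went the other way.

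Growth-factor-responsive genes such as FOSL1 and MYC were among the larger decreases, and a candidate explanation is weaker ERK signalling in the siRNA cells. The median of the ERK output genes lay at percentile 1.34 of 10000 random lists matched on signal, which the explanation needed. Percentiles as extreme were not rare among the planned lists, as for iron metabolism (99.87) and apolipoproteins and lipid transport (99.98), neither called by camera. The percentile alone therefore says little for the explanation. A difference in handling, serum or density at harvest may also lower immediate-early genes, and their median lay at percentile 0, with no random list as low. Random lists do not allow for correlation among a list's genes. Camera gave an adjusted p of 0.00129 (ERK output) and 8.26e-08 (immediate-early) with the preset correlation, and 0.225 for both with an estimated one. The estimated version has 1 residual degree of freedom, so it cannot tell whether correlation accounts for these medians. Both explanations stay open, since immediate-early genes are themselves targets of ERK and the labels record no harvest conditions, as does the targeting of MELTF, untested against a property of the scrambled array.

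The second pattern concerns MELTF, whose brightest probe set was lower and second brightest higher. Such a gap (1.17 on the log2 scale) was reached by 4.259% of 17913 pairs of probe sets of one gene, under the 5% set for it. The pair was taken up because its disagreement had been seen, and MELTF has other pairs, so this share cannot exclude usual disagreement. The median of the 29 nearest measured genes lay at percentile 0.413 of the medians around every other gene, each over up to 20 genes on each side. Most other genes had more such neighbours than MELTF, and medians of fewer genes vary more, so the percentile is only approximate. A lower level shared by the region, as a copy number difference would give, may account for much of the lower signal of the brightest probe set. It would not by itself explain the higher signal of the second brightest. Whether the siRNA lowered MELTF beyond its neighbours (difference -0.26, against an SE of 0.17 for MELTF) was not resolved with 3 arrays.

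The lower level reached past those neighbours: the lowest median of any 51 consecutive measured genes, -0.63, ran from YEATS2 to XXYLT1, which adjoins ACAP2. The highest, 0.71, ran from CPNE8 to MCRS1, with 46 of 51 genes above 0. The largest departure from the median of all genes in 100 shuffles of gene order was 0.44. Neighbouring genes correlated at 0.143 in their difference between siRNA and scrambled arrays, against at most 0.031 in shuffles, and at 0.080 in the difference between the 2 siRNA arrays.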
